A study of Mus musculus with 5 samples.

How the data were processed

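Cells of un-wounded (2 libraries) and wounded (3 libraries) C57BL/6 mouse skin were captured with 10x Genomics 3' v1 chemistry after a sort for live cells, and sequenced on an Illumina HiSeq, per the labels. The deposited matrices hold raw UMI counts per gene and cell barcode, made with Cell Ranger 1.3.1 on build mm10 per the submitters' processing notes. Barcodes had been filtered before deposit by a step that the notes do not state, since the least deep barcode of each library holds over 1000 UMIs. No normalised values or cell annotations were used, and the annotation behind the counts is not named. Gene positions come from a GRCm38 annotation matched by Ensembl ID (27645 IDs, 98.7% of the table), and 314 of 315 named or listed genes had one.

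Cells were kept with at least 200 genes and at most 10% mitochondrial UMIs, which removed 59 and 5 barcodes of wounded libraries 2 and 3 for few genes, and 108 and 143 un-wounded and 62, 72 and 23 wounded barcodes for mitochondrial UMIs. Doublets were scored with Scrublet in scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 barcodes (226 and 237 un-wounded, 456, 172 and 137 wounded cells). Counts were scaled to 10000 per cell and log-transformed; 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 gave 32 clusters, without integration of libraries. A cluster took the name of the cell type with the highest marker score when at least 3 markers reached 10 CPM and the next type scored at least 0.5 lower. This margin was set after the scores were seen. It left 26 clusters named and 6 unnamed, and 5 fixed markers were missing from the table. Shares of cells carry exact Clopper-Pearson 95% intervals per library, and groups were compared by exact two-sided permutation tests over 10 assignments of libraries. For a count of 0 the limit is 3 counts.

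UMIs were summed per library over all kept cells and over 3 of the 6 classes set for testing beforehand, basal keratinocytes, spinous keratinocytes and fibroblasts, which had at least 30 cells in every library. The sums were fitted with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F-test) in R 4.3.3, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. The difference of the wound effect between fibroblasts and basal keratinocytes was fitted as an interaction with library as a block. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and at an estimated one. Printed CPM are plain library CPM, while log2 fold changes carry TMM scaling. The named genes follow a rule: adjusted p under 0.05, absolute log2 fold change of at least 1, at least 50 CPM in the higher group, no overlap between groups, and CPM of at least 33.3% of that in every other named class. Mitochondrial, ribosomal, Gm-number and Rik genes were left out, and the 6 largest rises and 6 largest falls that passed were named. The 3 most abundant members of each list were named too, changed or not.

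Pipelines were tested on simulated data made from these libraries, with 200 genes changed. For a 4-fold change the share recovered was 0% in whole libraries, 78% in basal and 75% in spinous keratinocytes, 84% in fibroblasts and 55% for the interaction. For a 2-fold change it was 0, 21, 21, 20 and 4%, and 13 of 112, 6 of 102, 15 of 119 and 10 of 69 calls were false in basal, spinous, fibroblast and interaction tests. Replicates of a group differed far beyond counting error, with a chi-square per degree of freedom between 113 and 326.

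Basal keratinocytes were thinned to 1500 UMIs and counted as proliferating with UMIs of at least 2 of 18 listed genes; 2 shallower cells of un-wounded library 1 were left out. They were also split at Leiden resolution 0.5 into 5 sub-clusters, after the 209 genes called changed in basal sums were left out. Alternatives were DESeq2 1.42.0, no filter on low counts, no TMM, the replicate number as a block, doublets kept or called by Scrublet's own threshold, a mitochondrial limit of 5%, a minimum of 500 genes, Leiden resolution 2.0 (46 clusters), leaving out genes over 10 times higher in another class, and leaving out each library. Chosen after seeing the data were clusters named without a score margin, sums without the 2 highest cells of each gene in each library, and fibroblast sums without clusters 21 and 22, whose share of kept cells was over 3 times higher in wounded libraries. Macrophages, vascular endothelial cells and T cells, the other 3 classes set beforehand, were not tested, since some library held under 30 of them. Results of some genes are not reported here. Other tools were Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.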

Results

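RNA was counted in single cells of C57BL/6 mouse skin, captured in droplets with 10x Genomics 3' chemistry after sorting for live cells. The libraries fall into 2 groups, un-wounded skin (n = 2) and wounded skin (n = 3). Wounded skin had been punched to a width of 6 mm at 7 weeks of age, and a 10-mm disc around the wound was taken 4 days later. The tables held 5372 and 5517 cell barcodes for the un-wounded libraries, and 7578, 4698 and 4152 for wounded libraries 1, 2 and 3. Total counts of unique molecular identifiers (UMIs) were 33642571 and 41041406 for un-wounded, and 59621412, 33537809 and 41654423 for wounded skin. After filtering, 5038 and 5137 un-wounded and 7060, 4395 and 3987 wounded cells were kept. Kept cells had median depths of 6033.5 and 6828 UMIs in un-wounded and 6666.5, 6069 and 7940 in wounded libraries. The series title sets the question, how cells of adult skin differ between homeostasis and wound repair. Expression is given as CPM, the standard scaling of a gene's UMIs by the summed UMIs of its cell class, as mean ± SD over 2 un-wounded and 3 wounded libraries. Log2 fold changes (wounded over un-wounded, ± SE) and adjusted p come from edgeR, and a bare number in brackets after a gene is its log2 fold change. These p-values measure the spread between libraries, since the labels do not say whether each library is a separate animal. Confidence intervals and limits from counts of 0 cover counting error only. Gene positions are on build GRCm38 (mm10). Gene lists, cell type markers, filters and tests between groups were fixed before the data were examined. The score margin for naming clusters, sums without the 2 highest cells of each gene and sums without fibroblast clusters 21 and 22 were chosen after. List members named beyond the 3 most abundant of each list were chosen after their values were seen.

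Basal and spinous keratinocytes averaged a smaller share of wounded skin and macrophages and dendritic cells a larger one, although 10 assignments of libraries to groups allow no two-sided exact permutation p under 0.1. Basal keratinocytes, the dividing layer of the epidermis, averaged 31.2 ± 18.2% of un-wounded and 8.67 ± 11.4% of wounded cells (exact p = 0.3). Their share was 18.3% in un-wounded library 2 and 21.7% in wounded library 1, so the groups overlapped. Spinous keratinocytes, the differentiating layer above the basal one, averaged 17.2 ± 4.57% and 5.61 ± 5.48% (exact p = 0.2). Macrophages or monocytes averaged 0.419 ± 0.481% and 12.3 ± 10.1% (exact p = 0.2). Their share was 0.0794% (0.0216 to 0.203%) and 0.759% (0.5404 to 1.04%) in the un-wounded libraries, with exact Clopper-Pearson 95% intervals. It was 4.02% (3.58 to 4.51%), 9.42% (8.57 to 10.3%) and 23.5% (22.2 to 24.9%) in wounded libraries 1, 2 and 3. Dendritic cells averaged 1.25 ± 1.21% and 11.6 ± 8.65% (exact p = 0.2), and the class named NK cells 1.83 ± 1.71% and 5.94 ± 5.08% (exact p = 0.4). No neutrophil or mast cell was found in un-wounded skin, which allows shares of up to 0.0595 and 0.0584%, against 1.51 ± 1.296% and 0.644 ± 0.4700% of wounded cells (exact p = 0.3 and 0.2).

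The smallest p the design allows, exact p = 0.1, was reached by 4 classes. The class named T cells, 1 cluster of 186 cells led by Cd3g, Cd3e and Cd7, averaged 1.33 ± 0.894% of un-wounded and 0.328 ± 0.113% of wounded cells, and outer root sheath or bulge keratinocytes of the hair follicle 4.84 ± 3.200% and 1.55 ± 0.452%. Skeletal muscle cells averaged 0.0887 ± 0.0429% and 1.303 ± 0.318%, and unnamed clusters 13.9 ± 2.62% and 7.003 ± 1.77%. Fibroblasts averaged 24.9 ± 21.6% and 36.7 ± 6.03% (exact p = 0.5), with 9.59 and 40.2% in the un-wounded libraries. Pericytes or smooth muscle cells averaged 0.778 ± 0.275% and 3.72 ± 4.12% (exact p = 0.6), and vascular endothelial cells 0.383 ± 0.00863% and 1.41 ± 0.828% (exact p = 0.2). Sebocytes averaged 1.27 and 1.08% (exact p = 0.8), and Langerhans cells 0.665 and 0.6502% (exact p = 1). Langerhans cells made up 1.33 and 0% of un-wounded libraries 1 and 2, and 1.52, 0.159 and 0.276% of wounded libraries 1, 2 and 3. Sebocyte shares were likewise highest in library 1 of each group, at 1.77 and 2.35%. Single libraries set the size of many differences. Without un-wounded library 1 the basal difference was -9.63 percentage points instead of -22.5, that of T cells -0.372 instead of -1.005, and that of fibroblasts -3.54 instead of 11.8. Without un-wounded library 2 the fibroblast difference was 27.1, the basal difference -35.4, and that of outer root sheath or bulge cells -1.03 instead of -3.29. The macrophage difference was 6.302 without wounded library 3 instead of 11.9. Dendritic and NK cell differences were 5.83 and 1.49 without wounded library 2 instead of 10.3 and 4.12. Without un-wounded library 1 that of outer root sheath or bulge cells was -5.55, and without un-wounded library 2 that of T cells was -1.64. Without wounded library 1 the difference was 6.56 for NK cells and 0.609 for pericytes or smooth muscle cells instead of 2.94. Without wounded library 2 it was 4.51 for pericytes or smooth muscle cells and 0.761 for neutrophils instead of 1.51. Without wounded library 3 it was 0.587 for endothelial cells instead of 1.02, and 0.376 for mast cells instead of 0.644. Leaving out un-wounded library 1, un-wounded library 2 and wounded libraries 1, 2 and 3 gave 0.303, -0.685, -0.826, 0.179 and 0.0737 for sebocytes instead of -0.191, and 0.6502, -0.6796, -0.447, 0.231 and 0.172 for Langerhans cells instead of -0.0147. At a finer clustering (Leiden resolution 2.0) the T cell difference turned to 0.891, that of NK cells was 1.68 and that of unnamed clusters -2.41. With no score margin, chosen after seeing the data, that of unnamed clusters turned to 0.282. At resolution 2.0, 584 of the 976 cells of the class named NK cells fell in a cluster named T cells, led by Icos and Cxcr6, and 309 in one named NK cells. The class named NK cells thus holds T cells, and the class named T cells leaves them out. Of 9 T cell markers 4 were missing from the tables.

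**Figure D1:**
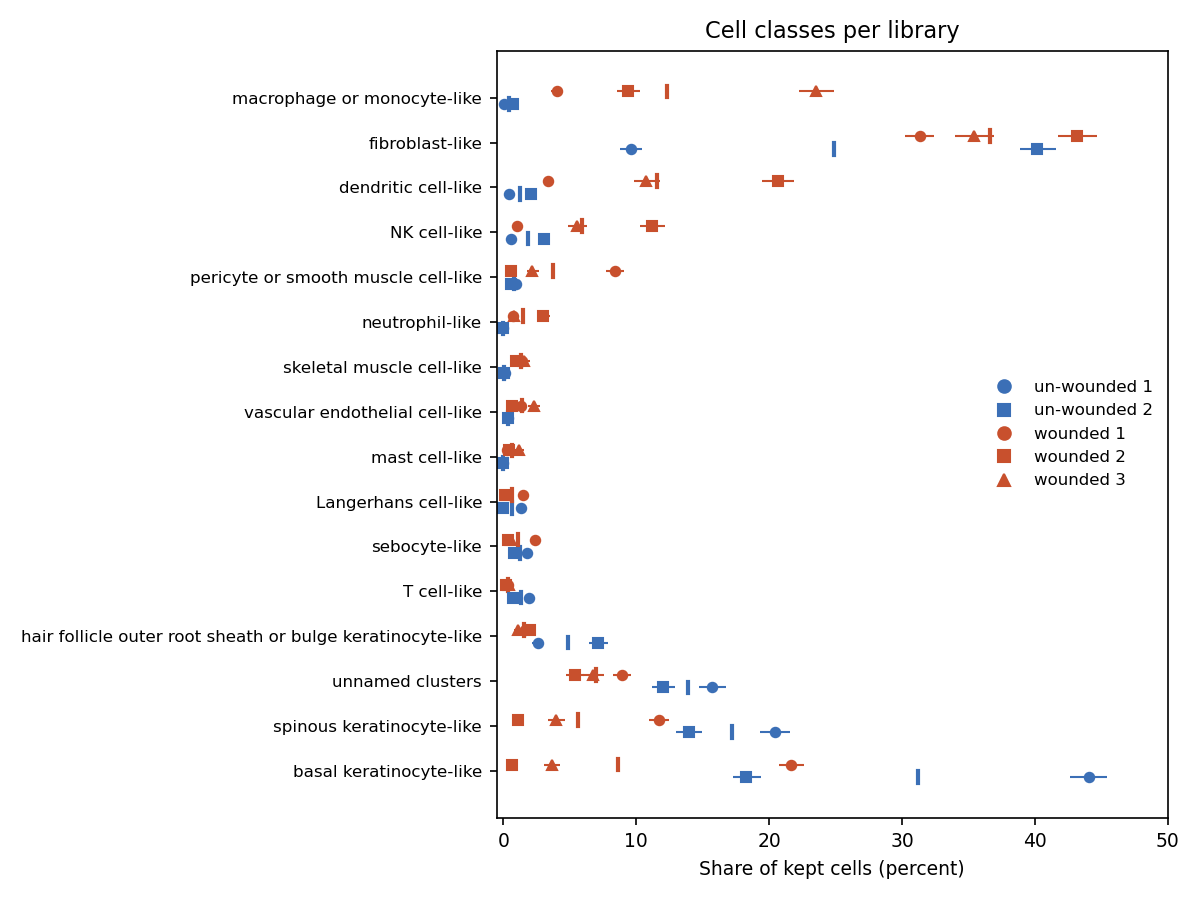
Share of kept cells (percent) held by each cell class in the 2 un-wounded and 3 wounded libraries, with 1 point per library, 95% exact binomial intervals as error bars and short bars at group means. Basal and spinous keratinocytes lie lower in the means of wounded skin, macrophages and dendritic cells higher, and neutrophils and mast cells lie at 0 in both un-wounded libraries.

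Summed over all cells, wounded skin held far more RNA of the neutrophil attractants Cxcl5 and Cxcl3, of the calprotectin subunits S100a8 and S100a9, and of Hdc and Cma1. Cxcl5, a chemokine that draws neutrophils (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624), had 1 UMI in un-wounded libraries and 171 ± 119 CPM in wounded ones. Its pooled CPM ratio was 12522 (2247 to 494607), by exact counting interval (log2 fold change 13.31 ± 1.41, adjusted p = 0.0459). S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721) rose from 0.286 ± 0.000922 to 334 ± 174 CPM (log2 fold change 10.23 ± 0.92, adjusted p = 0.0441), and S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035) from 0.581 ± 0.688 to 276 ± 103 CPM (log2 fold change 8.94 ± 1.15, adjusted p = 0.047). Cxcl3, another neutrophil attractant (ENSMUSG00000029379), rose by 9.74, adjusted p = 0.0459. Hdc, which makes histamine, and the mast cell chymase Cma1 rose by 7.5, adjusted p = 0.0459, and 7.48, adjusted p = 0.0394. Gpha2, a glycoprotein hormone subunit (ENSMUSG00000024784, chromosome 19, 6226380 to 6227768), was the sole fall named, from 80.4 ± 8.22 to 18.6 ± 4.45 CPM (log2 fold change -2.10 ± 0.28, adjusted p = 0.0487). It overlaps Ppp2r5b on the other strand, so its reads are uncertain at shared bases. For each of these genes all 3 wounded libraries lay on 1 side of both un-wounded ones, as the rule for naming required. In all, 94 of 15497 genes changed, 91 higher and 3 lower in wounded skin, and 4009 had an unadjusted p under 0.05. Groups did not overlap in 7152 genes (46.2%), against a chance share of 20%.

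Of 12 tested type I interferon response genes 6 rose in whole libraries, among them Ifi27l2a (48.5 to 702 CPM, log2 fold change 3.92, adjusted p = 0.0462) and Isg15 (3.71, adjusted p = 0.0462), and 10 rose adjusted over the list alone (camera adjusted p = 5.79e-09, and adjusted p = 0.271 with an estimated correlation). Of 12 chemokines and cytokines, Cxcl5 and Cxcl1 (5.67) rose, and 11 adjusted over the list alone (camera adjusted p = 4.29e-07, and adjusted p = 0.271 with an estimated correlation). Of 13 wound-activated keratinocyte genes 4 rose, Krt6b (7.69), Sprr1b (4.93), S100a8 and S100a9, and 7 adjusted over the list alone (camera adjusted p = 0.000154, and adjusted p = 0.271 with an estimated correlation). Of 17 collagens and matrix genes, Tnc, a matrix glycoprotein of wound beds, rose by 5.78, and 3 rose adjusted over the list alone (camera adjusted p = 7.09e-05, and adjusted p = 0.444 with an estimated correlation). Cell type markers moved with these groups. Of 8 neutrophil markers 3 rose, S100a8, S100a9 and Hdc, and 7 adjusted over the list alone (camera adjusted p = 1.55e-06, and adjusted p = 0.271 with an estimated correlation). S100a8 and S100a9 are also in the wound-activated keratinocyte list, and Hdc was a leading gene of the mast cell cluster. Of 7 skeletal muscle markers 3 rose, Mylpf (3.79), Tnnt3 (3.90) and Ckm (3.74), and all 7 adjusted over the list alone (camera adjusted p = 5.2e-07, and adjusted p = 0.271 with an estimated correlation). None of 11 macrophage markers passed over all genes, against 10 that rose adjusted over the list alone (camera adjusted p = 1.71e-05, and adjusted p = 0.399 with an estimated correlation). None of 7 MHC class II genes passed, such as H2-Aa (2.79, adjusted p = 0.078), against 7 adjusted over the list alone (camera adjusted p = 0.000107, and adjusted p = 0.399 with an estimated correlation). None of 8 basal keratinocyte markers passed, with Krt5 at -1.92, adjusted p = 0.25, while 5 fell adjusted over the list alone (camera adjusted p = 0.000199, and adjusted p = 0.405 with an estimated correlation). Of 12 epidermal differentiation genes none passed, and Lor (-2.41) and Calml3 (-2.09) fell adjusted over the list alone (camera adjusted p = 0.000377, and adjusted p = 0.444 with an estimated correlation). No member passed among 12 hair follicle keratinocyte genes (camera adjusted p = 0.00836, and adjusted p = 0.399 with an estimated correlation) or 18 glycolysis and hypoxia genes (camera adjusted p = 0.0486, and adjusted p = 0.529 with an estimated correlation). None passed either among 18 oxidative phosphorylation genes (camera adjusted p = 0.825), 18 proliferation genes (camera adjusted p = 0.657) and 4 erythroid markers (camera adjusted p = 0.823).

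The whole-library count rested on single libraries. Without un-wounded library 1, un-wounded library 2 or wounded library 3, edgeR called 0 genes, with 2179, 4592 and 2048 at an unadjusted p under 0.05, so every whole-library call above was lost. Without wounded library 1 it called 2141, and DESeq2 called 2657 with all libraries, 1919 higher and 738 lower. Without wounded library 2 the calls of S100a8 (adjusted p = 0.0632), Hdc (0.0526), Gpha2 (0.0653), Ifi27l2a (0.0662) and Isg15 (0.0613) were also lost. On simulated libraries of the same design and spread, the whole-library test recovered 0% of genes changed 4-fold.

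In basal keratinocytes of wounded skin, genes of the stefin A family, stress keratins, a cornified envelope gene and the chemokine Ccl20 rose. BC100530, a stefin A family cysteine protease inhibitor (ENSMUSG00000071561, chromosome 16, 36359382 to 36367748), rose from 7.298 ± 7.47 to 1437 ± 1180.5 CPM (log2 fold change 7.83 ± 0.91, adjusted p = 8.74e-06). Its family members Stfa1 (ENSMUSG00000071562, chromosome 16, 36276951 to 36285373) and Stfa3 (ENSMUSG00000054905, chromosome 16, 36450537 to 36455392) rose by 7.03, adjusted p = 1.46e-05, and 6.24, adjusted p = 4.56e-05. Krt6a, a keratin of activated epidermis (ENSMUSG00000058354, chromosome 15, 101689910 to 101694307), rose from 2.33 ± 2.51 to 193 ± 153 CPM (log2 fold change 6.66 ± 0.81, adjusted p = 1.46e-05). Ccl20, which attracts lymphocytes and dendritic cells (ENSMUSG00000026166, chromosome 1, 83116766 to 83119167), rose from 11.99 ± 4.98 to 156 ± 56.8 CPM (log2 fold change 3.73 ± 0.37, adjusted p = 9.35e-07). Sprr2a3, a small proline-rich protein of the cornified envelope (ENSMUSG00000074445), rose by 4.72, adjusted p = 0.00024. Fewer genes fell. Gpha2 fell from 106 ± 11.1 to 34.3 ± 11.4 CPM (log2 fold change -1.601 ± 0.29, adjusted p = 0.00169), and the cystatin Cst6, the calcium channel subunit Cacnb3 and PISD, which has no position in the annotation used, had log2 fold changes of -1.25, adjusted p = 0.0358, -1.14, adjusted p = 0.0318, and -1.09, adjusted p = 0.039. All 3 wounded libraries lay on 1 side of both un-wounded ones in each of these 10 genes, as the rule for naming required. Few cells held much of the RNA of the rising genes, since the 2 highest cells of each wounded library held 53.5% of the wounded Krt6a UMIs, 47.2% for Stfa1, 35.99% for BC100530, 35.7% for Sprr2a3, 28.4% for Stfa3 and 20.5% for Ccl20. For Cst6, 575 of the 895 UMIs of un-wounded library 2 lay in 2 cells. Reads shared between paralogs (Krt6a and Krt6b, BC100530 and Stfa genes, Sprr2 genes) leave the split between family members uncertain, and BC100530 overlaps Gm15845.

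In all, 209 of 11292 genes changed in basal keratinocytes, 194 higher and 15 lower in wounded skin, and 1031 had an unadjusted p under 0.05. Groups did not overlap in 3323 genes (29.4%), against a chance share of 20%. These sums held 2219 and 940 un-wounded cells and 1531, 30 and 145 wounded ones, with 223565 UMIs in wounded library 2, the shallowest, and 14379629 in un-wounded library 1. Their clusters were mixed differently, since cluster 15 held a mean of 9.56 and 5.64% of kept un-wounded and wounded cells, cluster 4 10.6 and 0.806%, cluster 1 8.26 and 1.08% and cluster 3 2.79 and 1.14%. Of the 209 genes, 135 had over 10 times higher CPM in another cell class, and 75 changed among genes without such a class. DESeq2 called 122 genes, edgeR without TMM scaling 129, and edgeR without wounded library 3 131. TMM scaling mattered, since without it the median log2 change of all genes was -0.22 in basal and -0.22 in spinous keratinocytes instead of -0.08 and -0.04. Cluster 12 (Sostdc1, Vsnl1) was left unnamed for its close marker scores, and counting it as basal, chosen after seeing the data, left 59 changed genes and ended the calls of Gpha2 (adjusted p = 0.0809), Krt16 (0.33), Krt17 (0.373), Stfa3 (0.0729) and Sprr2a3 (0.103). The calls of Cst6, Cacnb3 and PISD ended with DESeq2 (adjusted p = 0.166, 0.159 and 0.147). They also ended without un-wounded library 2 (0.927, 0.127 and 0.38) and without wounded library 3 (0.206, 0.323 and 0.285). Further losses were Cacnb3 and PISD without un-wounded library 1 (0.0978 and 0.07), Cst6 and Cacnb3 without wounded library 2 (0.0635 and 0.0535), and PISD without wounded library 1 (0.142). Without the 2 highest cells of each gene Cst6 (0.683) and PISD (0.0753) were lost too. Sprr2a3 had 2.53 without wounded library 3.

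Of 13 tested wound-activated keratinocyte genes 10 rose in basal keratinocytes, and 11 adjusted over the list alone (camera adjusted p = 4.54e-15, and adjusted p = 0.113 with an estimated correlation). Besides Krt6a these included Krt16 (128 ± 57.7 to 411 ± 174 CPM, log2 fold change 1.86, adjusted p = 0.00495) and Krt17 (1.604, adjusted p = 0.0168), stress keratins, and Areg, a growth factor that activates the EGF receptor (2.46). The pooled CPM ratio was 213 (72.4 to 1039) for S100a8, 396 (109 to 3282) for S100a9 and 144 (39.3 to 1199.5) for Sprr1b, each from 2 or 3 un-wounded UMIs. The call of Krt16 was lost without un-wounded library 1 (adjusted p = 0.0912), and that of Krt17 without un-wounded library 2 (0.122) or wounded library 3 (0.093). Of these 13 genes, 9 had over 10 times higher CPM in another class. Markers of other cell types moved with them. Of 5 neutrophil markers 4 rose, S100a8, S100a9, Hdc (4.08) and Retnlg (at least 15.4-fold higher), 4 adjusted over the list alone (camera adjusted p = 2.29e-07, and adjusted p = 0.113 with an estimated correlation). S100a8 and S100a9 belong to this list and to the wound-activated one. Of 7 macrophage markers Lyz2, a lysozyme, rose by 1.83, adjusted p = 0.036, and 2 rose adjusted over the list alone (camera adjusted p = 0.00336, and adjusted p = 0.223 with an estimated correlation). For Lyz2 the groups overlapped, and its call was lost without un-wounded library 1 (adjusted p = 0.175) or wounded library 3 (0.924), with DESeq2 (0.176) and without TMM (0.14). None of 8 fibroblast markers passed (camera adjusted p = 0.72), with a median log2 change of -0.22, a mean of 0.01 and an upward test. None of 3 erythroid markers passed (camera adjusted p = 0.499), with a median of -0.02 and an upward test. With doublets kept, the globins Hba-a2 (13.77, adjusted p = 0.0294) and Hba-a1 (12.54, 0.0378) passed the test in basal sums on wounded library 2 alone. Its 38 cells, 8 of them added, held 10427 and 13080 UMIs, against at most 3 and 7 in each other wounded and 13 and 35 in each un-wounded library.

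Of 9 interferon response genes, Isg15 (1.80, adjusted p = 0.00512) and Ifit1 (2.48, adjusted p = 0.039) rose in basal keratinocytes, and 5 adjusted over the list alone (camera adjusted p = 0.000195, and adjusted p = 0.113 with an estimated correlation). Of 18 glycolysis and hypoxia genes, the hexokinase Hk2 (2.46, adjusted p = 0.00772) and the oxygen sensor Egln3 (1.75, adjusted p = 0.0447) rose, and 4 adjusted over the list alone (camera adjusted p = 9.95e-08, and adjusted p = 0.153 with an estimated correlation). Of 8 mesenchymal genes 2 rose, among them the collagenase Mmp13 (at least 45.2-fold higher), and 3 adjusted over the list alone (camera adjusted p = 0.000466, and adjusted p = 0.113 with an estimated correlation). Vim, the mesenchymal filament protein, had 0.91, adjusted p = 0.264. Over 10 times higher CPM in another class was seen for 6 of the 9 interferon and 7 of the 18 glycolysis and hypoxia genes. The same held for 7 of the 8 mesenchymal genes. None of 18 proliferation genes passed, with Ube2c at 1.01, adjusted p = 0.0589, which alone rose adjusted over the list alone (camera adjusted p = 3.72e-05, and adjusted p = 0.117 with an estimated correlation). None of 18 oxidative phosphorylation genes passed, with Cox4i1 at 0.16 (camera adjusted p = 0.00928, and adjusted p = 0.569 with an estimated correlation). Of 7 hair follicle keratinocyte genes, the stem cell regulator Sox9 rose by 1.68 and Cst6 fell, with 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.499). Their median was -0.21, against a mean of 0.30 and an upward test. Of these 7 genes, 6 had over 10 times higher CPM in another class. None passed among 12 hemidesmosome genes, which anchor basal cells, such as Col17a1 (-0.25, adjusted p = 0.893; camera adjusted p = 0.575). Among 16 immediate early genes none passed, such as Fos (-0.66, adjusted p = 0.64; camera adjusted p = 0.72). Of 11 differentiation genes none passed, such as Krt10 (-0.29, adjusted p = 0.863), and 1 rose adjusted over the list alone (camera adjusted p = 0.586).

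The share of basal keratinocytes with UMIs of at least 2 of 18 proliferation genes, after thinning each cell to 1500 UMIs, averaged 19.98 ± 1.08% in un-wounded (n = 2) and 22.6 ± 1.29% in wounded skin (n = 3; exact p = 0.2). It was 19.2% (17.6 to 20.9%) and 20.7% (18.2 to 23.5%) in the un-wounded libraries, and 21.2% (19.1 to 23.3%), 23.3% (9.93 to 42.3%) and 23.4% (16.8 to 31.2%) in wounded libraries 1, 2 and 3. These counting intervals overlapped. Without thinning the shares were 62.8 and 66.2% (exact p = 0.9). With at least 1 gene asked for they were 52.1 and 53.8% (exact p = 0.4), a difference of 1.69 points instead of 2.67. The difference was 3.91 points with thinning to 1000 UMIs (exact p = 0.3) and 3.82 with a mitochondrial limit of 5% (exact p = 0.2). It was 3.27 with doublets kept (exact p = 0.2) and 2.80 at Leiden resolution 2.0 (exact p = 0.1). As a background, 0 of 97, 0 of 42 and 1 of 63 skeletal muscle cells of the wounded libraries passed the same count. Basal keratinocytes also split into 5 sub-clusters, drawn without the 209 genes called changed in basal sums. Sub-cluster 4, led by the AP-1 member Fosl1 with Ifrd1, Pmp22 and Serpinb2, averaged 8.19 ± 4.36% of un-wounded and 34.2 ± 10.4% of wounded basal cells (exact p = 0.2). Sub-cluster 0, led by the mitotic genes Ube2c and Cenpa, averaged 10.7 ± 5.15 and 17.7 ± 5.83% (exact p = 0.3), a difference of 7.01 points that was 3.36 without un-wounded library 1 and 10.6 without un-wounded library 2. Sub-clusters 1 (Ikzf2, Pdzd2), 2 (Gm42418, Usp34) and 3 (Klf2, Btg2, Fos) differed by -8.705, -14.4 and -9.91 points (exact p = 0.7, 0.7 and 0.6). These differences were 7.09, -46.4 and 6.88 without un-wounded library 1, and -24.5, 17.6 and -26.7 without un-wounded library 2. Those of sub-clusters 2 and 3 were -5.66 and -17.2 without wounded library 1, and -26.7 and -2.57 without wounded library 2.

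Spinous keratinocytes of wounded skin showed large rises of stress keratins and cornified envelope genes. Krt16 (ENSMUSG00000053797, chromosome 11, 100246091 to 100248902) rose from 59.1 ± 18.7 to 1205 ± 562 CPM (log2 fold change 4.57 ± 0.52, adjusted p = 0.000172), and Krt6a from 0.319 ± 0.0845 to 390.3 ± 359 CPM (log2 fold change 10.31 ± 1.01, adjusted p = 6.11e-05). Krt6b (ENSMUSG00000023041, chromosome 15, 101676023 to 101680287), with 1 un-wounded UMI, had a pooled CPM ratio of 4677 (839 to 184792) (log2 fold change 12.91 ± 1.05, adjusted p = 1.59e-05). Sprr2d (ENSMUSG00000042212, chromosome 3, 92339140 to 92340873) had no un-wounded UMI and was at least 366-fold higher, against a floor of 3 counts over the group (adjusted p = 6.2e-06). Sprr1b (ENSMUSG00000048455) rose from 1.74 to 382 CPM (7.91, adjusted p = 0.000174), Sprr2a3 from 0.512 to 89.9 CPM (7.55, adjusted p = 5.4e-05) and BC100530 from 3.86 to 2472 CPM (9.48, adjusted p = 0.000359). Trim2, a ubiquitin ligase (ENSMUSG00000027993, chromosome 3, 84160439 to 84306877), was the sole fall named, from 55.03 ± 5.12 to 16.1 ± 6.69 CPM (log2 fold change -1.40 ± 0.29, adjusted p = 0.0206). In each of these genes all 3 wounded libraries lay on 1 side of both un-wounded ones, which the rule for naming required of the genes it picked. Few cells held most of the wounded UMIs of Sprr2d, Krt6b, Krt6a, Sprr1b, Sprr2a3 and BC100530. The 2 highest cells of each wounded library held 98.3% of the wounded Sprr2d UMIs, 89.9% for Krt6b, 85.5% for Krt6a, 77.1% for Sprr1b, 58.1% for Sprr2a3 and 57.1% for BC100530.

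In all, 198 of 10918 genes changed in spinous keratinocytes, 190 higher and 8 lower in wounded skin, and 991 had an unadjusted p under 0.05. Groups did not overlap in 3011 genes (27.6%), against a chance share of 20%, and 110 of the 198 had over 10 times higher CPM in another class. Without such genes 103 changed. The sums held 1029 and 717 un-wounded cells and 828, 50 and 158 wounded ones, with 473109 to 7917156 UMIs. Cluster 0 of this class, whose leading genes include Krt6b, Sprr1b and Krt16, held 42 and 28% of the class in un-wounded and 77, 42 and 78% in wounded libraries. Krt6b does not mark its un-wounded cells, since all un-wounded spinous keratinocytes together held 1 UMI of this gene. Calls fell to 41 without un-wounded library 1, 72 without un-wounded library 2 and 113 without wounded library 3, and were 301 without wounded library 1. The call of Trim2 was lost without un-wounded library 1 (adjusted p = 0.135), un-wounded library 2 (0.188) or wounded library 3 (0.0675), and that of BC100530 without un-wounded library 1 (0.0505).

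Of 13 wound-activated keratinocyte genes 9 rose in spinous keratinocytes, and all 13 adjusted over the list alone (camera adjusted p = 3.69e-21, and adjusted p = 0.123 with an estimated correlation). Besides the genes above these included Krt17 (2.76, adjusted p = 0.0364), S100a8 (0.452 to 949 CPM, 11.09, adjusted p = 0.000172) and S100a9 (9.70, adjusted p = 7e-05). The 2 highest cells per library held 93.1% of wounded S100a8 and 82.6% of S100a9 UMIs. Of 4 neutrophil markers 3 rose, S100a8, S100a9 and Hdc (ratio 50.02 (8.36 to 2037)), 3 adjusted over the list alone (camera adjusted p = 2.43e-07, and adjusted p = 0.123 with an estimated correlation). S100a8 and S100a9 belong to both lists, so the 2 results are not separate. Hdc was also a leading gene of the mast cell cluster. Of 4 macrophage markers Cd68 (2.78, adjusted p = 0.025) and Lyz2 (2.63, adjusted p = 0.0439) rose, and 4 adjusted over the list alone (camera adjusted p = 0.000685, and adjusted p = 0.225 with an estimated correlation). Both calls were lost without un-wounded library 1 (adjusted p = 0.186 and 0.589), un-wounded library 2 (0.263 and 0.125) or wounded library 3 (0.251 and 0.658). None of 7 fibroblast markers passed (camera adjusted p = 0.64), with a median of -0.35, a mean of -0.08 and an upward test. None of 4 erythroid markers passed, while Hbb-bs (3.40) and Hbb-bt (3.59) rose adjusted over the list alone (camera adjusted p = 0.0537).

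Of 12 differentiation genes, the envelope protein gene Ivl rose by 1.90, adjusted p = 0.00838, also the sole one adjusted over the list alone (camera adjusted p = 0.00212, and adjusted p = 0.123 with an estimated correlation), and Krt10 and Krtdap had 0.21, adjusted p = 0.951, and 0.31, adjusted p = 0.903. Of 18 glycolysis and hypoxia genes Hk2 (3.13), Egln3 (2.41) and the hypoxia-induced Ndrg1 (1.66) rose, and 4 adjusted over the list alone (camera adjusted p = 1.07e-08, and adjusted p = 0.123 with an estimated correlation). Of 8 interferon response genes Ifi27l2a rose by 2.47, adjusted p = 0.0105, and 5 adjusted over the list alone (camera adjusted p = 0.000194, and adjusted p = 0.123 with an estimated correlation). Of 7 mesenchymal genes 1 rose, and 2 adjusted over the list alone (camera adjusted p = 0.0318, and adjusted p = 0.344 with an estimated correlation). Of 6 hair follicle keratinocyte genes the defensin Defb6 rose by 2.33, adjusted p = 0.0335, and 2 adjusted over the list alone (camera adjusted p = 0.149). Over 10 times higher CPM in another class was seen for 6 of the 8 interferon and 7 of the 18 glycolysis and hypoxia genes. It was also seen for 6 of the 7 mesenchymal and 5 of the 6 hair follicle keratinocyte genes. Without un-wounded library 1 the calls of Ifi27l2a and Defb6 were lost (adjusted p = 0.301 and 0.538), as they were without un-wounded library 2 (0.0786 and 0.0953). Without wounded library 3 those of Ifi27l2a (0.0618) and Defb6 (0.106) were lost, and DESeq2 ended those of Lyz2 (0.367) and Defb6 (0.19). Without the 2 highest cells of each gene Defb6 (0.112) no longer passed, and Sprr2d, with too few UMIs left, was not tested. Krt6b, Krt6a, Krt16, Sprr1b, Sprr2a3, BC100530 and Trim2 then passed. None of 18 oxidative phosphorylation genes passed (camera adjusted p = 0.0324, and adjusted p = 0.348 with an estimated correlation). None passed among 12 hemidesmosome genes (camera adjusted p = 0.162), 16 immediate early genes such as Fos (-0.29; camera adjusted p = 0.341) or 17 proliferation genes (camera adjusted p = 0.994). The proliferation genes had a median of -0.15 and a mean of -0.02, against an upward test.

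**Figure D2:**
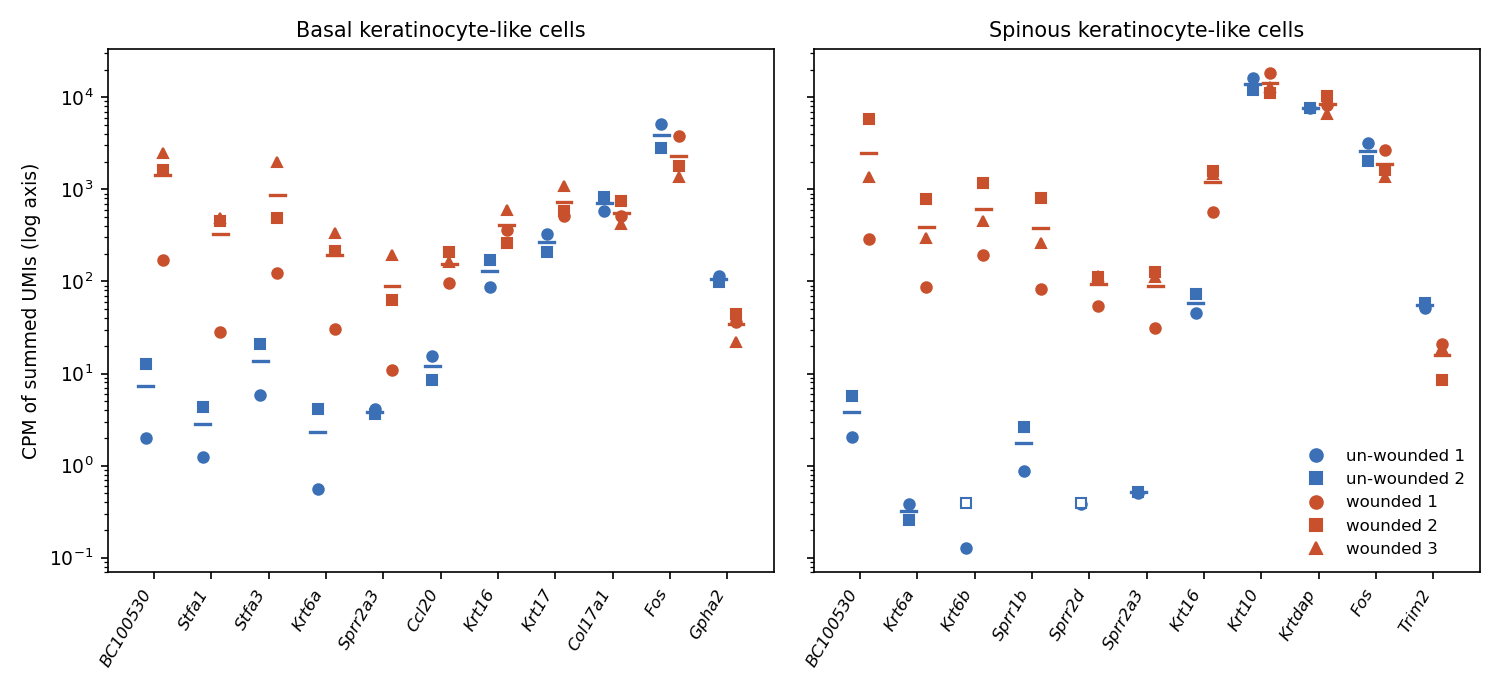
CPM (log axis) of named and listed genes in basal and spinous keratinocyte sums, with 1 point per library, un-wounded (n = 2) beside wounded (n = 3), group means as bars, and open symbols at the 3-count floor where a library held no UMI. Groups with an open symbol have no bar. Krt6a, BC100530 and Sprr2a3 lie higher in all 3 wounded libraries of both classes, while Col17a1 and Krt10 overlap.

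In wounded fibroblasts genes for neutrophil and monocyte attractants, an acute phase protein and some matrix proteins rose. Cthrc1, a secreted protein of matrix-forming fibroblasts (ENSMUSG00000054196, chromosome 15, 39076932 to 39087121), rose from 5.86 ± 0.355 to 635 ± 308 CPM (log2 fold change 6.83 ± 0.59, adjusted p = 0.000919). Cxcl5, with 1 un-wounded UMI, reached 395 ± 268 CPM, a pooled ratio of 6884 (1235 to 271907) (log2 fold change 12.58 ± 1.33, adjusted p = 0.00139). Saa3, an acute phase serum amyloid (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose from 1.28 ± 1.82 to 1525 ± 1436 CPM (log2 fold change 9.76 ± 1.20, adjusted p = 0.00241). Il1rl1, the receptor of interleukin 33 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415), rose from 0.174 to 100.3 CPM (8.46, adjusted p = 0.00103). Prg4, the joint lubricant lubricin (ENSMUSG00000006014, which overlaps Tpr), and the prostacyclin synthase Ptgis (ENSMUSG00000017969) rose by 7.49, adjusted p = 0.000449, and 7.07, adjusted p = 0.00103. Falls were smaller. Oxtr, the oxytocin receptor (ENSMUSG00000049112, chromosome 6, 112473683 to 112489943), fell from 70.4 ± 31.9 to 9.28 ± 2.32 CPM (log2 fold change -2.85 ± 0.33, adjusted p = 0.00185), and Bmp7, a bone morphogenetic protein (ENSMUSG00000008999, chromosome 2, 172868012 to 172940321), from 56.7 ± 2.201 to 14.8 ± 1.31 CPM (log2 fold change -1.84 ± 0.19, adjusted p = 0.00139). The peptidase inhibitor Pi15, the cytochrome P450 Cyp2f2, the matrix protein gene Vit and Gpha2 also fell, with log2 fold changes of -2.04, adjusted p = 0.00918, -1.75, adjusted p = 0.00375, -1.72, adjusted p = 0.00869, and -1.66, adjusted p = 0.00556. In each of these 12 genes all 3 wounded libraries lay on 1 side of both un-wounded ones, as the rule for naming required. In all, 998 of 13277 genes changed, 781 higher and 217 lower in wounded skin, and 2889 had an unadjusted p under 0.05. Groups did not overlap in 5336 genes (40.2%), against a chance share of 20%, and 344 of the 998 had over 10 times higher CPM in another class. The sums held 483 and 2065 un-wounded and 2212, 1899 and 1413 wounded cells, with 2319381 to 18919101 UMIs.

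Of 6 fibroblast clusters 2 were found mainly in wounded skin. Cluster 21, led by Cxcl5, Cthrc1, Ptx3, Saa3 and Timp1, held 0 and 1 un-wounded cells and 379, 157 and 375 wounded ones, or 33.4, 18.8 and 47.3% of the fibroblast UMIs of wounded libraries 1, 2 and 3. Cluster 22, led by Cxcl13, Thbs4 and C3, held 7 and 38 un-wounded and 424, 301 and 224 wounded cells, or 21.8, 20.6 and 16.04% of those UMIs against 1.17 and 2.72% in un-wounded libraries. Clusters 14, 16, 17 and 18 made up the rest of the class. By number, cluster 21 made up 17.1, 8.27 and 26.5% of the fibroblasts of wounded libraries 1, 2 and 3. Its cells were deep, with a median of 19151 UMIs, and weigh more in the sums than their number. Without clusters 21 and 22, chosen after seeing the data, 42 genes changed (36 higher, 6 lower; 1366 at an unadjusted p under 0.05), 41 of them among the 998 and 1 of these in the other direction. The clusters were drawn from expression, so leaving them out removes the cells highest in these genes, and a lost call does not show that a change came with them. Median log2 changes without them were 2.60 for chemokines and cytokines instead of 3.26 and -0.19 for proliferation genes instead of 1.97. Saa3 (8.83, adjusted p = 0.0431), Prg4 (5.11, 0.0466), Cthrc1 (2.70, 0.0466), Cxcl1 (2.98, 0.034), Ccl2 (2.22, 0.0303) and Ifi27l2a (2.56, 0.0383) still passed. Calls lost were those of Cxcl5 (7.12, 0.0829), Il1rl1 (4.08, 0.0618), Oxtr (-1.80, 0.0638), Bmp7 (-1.12, 0.0829), Pi15 (-1.71, 0.0851), Vit (-1.02, 0.13), Cyp2f2 (-0.69, 0.321) and Gpha2 (-0.60, 0.229). Calls numbered 550 without un-wounded library 1, 367 without un-wounded library 2 and 643 without wounded library 3, and Pi15 was lost without un-wounded library 2 (adjusted p = 0.0904). Un-wounded library 1 held no UMI of Saa3, Il1rl1, Prg4 and Ptgis. With un-wounded library 2 left out, these were at least 1201, 80.2, 46.7 and 47.1-fold higher, against a floor of 3 counts over the remaining un-wounded library.

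Of 12 chemokines and cytokines 11 rose in fibroblasts, and 11 adjusted over the list alone (camera adjusted p = 1.69e-09, and adjusted p = 0.118 with an estimated correlation). Cxcl1, a neutrophil attractant, rose from 53.1 to 2807 CPM (5.80, adjusted p = 0.00185), and the monocyte attractants Ccl2 and Ccl7 by 3.39, adjusted p = 0.00278, and 1.59, adjusted p = 0.0173. Ccl7 was not called without un-wounded library 1 (adjusted p = 0.135) or 2 (0.0722), and Ccl11 did not pass in the full set. Of 12 interferon response genes 9 rose, and 10 adjusted over the list alone (camera adjusted p = 6.37e-08, and adjusted p = 0.118 with an estimated correlation), among them Ifi27l2a (4.01, adjusted p = 0.00372), Isg15 (2.13, adjusted p = 0.0021) and Bst2 (1.58, adjusted p = 0.00469, 0.0658 without un-wounded library 2). Of 18 proliferation genes 10 rose, and 14 adjusted over the list alone (camera adjusted p = 6.37e-08, and adjusted p = 0.307 with an estimated correlation). Of these 18 genes, 8 had over 10 times higher CPM in another class. Birc5, a mitotic regulator, rose from 3.601 to 45.5 CPM (4.23, adjusted p = 0.00241), and the cyclin Ccna2 by 4.58, adjusted p = 0.00292. Stmn1 (2.01, adjusted p = 0.0338) was lost without un-wounded library 2 (adjusted p = 0.17), without wounded library 3 (0.071) and with doublets kept (0.0575). Of 9 contractile and myofibroblast genes 4 rose, the smooth muscle actin Acta2 (11.3 to 257 CPM, 4.56, adjusted p = 0.00255), Tagln (3.23), Actn1 (3.05) and Tpm2 (2.46), and 9 adjusted over the list alone (camera adjusted p = 5.54e-06, and adjusted p = 0.307 with an estimated correlation). Of these 9 genes, 6 had over 10 times higher CPM in another class. Of 13 matrix proteases and inhibitors 5 rose, among them the protease inhibitor Timp1 (52.1 to 907 CPM, 4.24, adjusted p = 0.00343), the metalloproteases Mmp13 (at least 34.2-fold higher) and Mmp19 (1.70), and Mmp9, with a ratio of 162 (28.9 to 6408) from 1 un-wounded UMI. Adjusted over the list alone 6 rose and 1 fell, Timp3 (-1.29; camera adjusted p = 0.000294, and adjusted p = 0.118 with an estimated correlation). Timp1 lies within Syn1 on the other strand.

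Of 17 collagens and matrix genes 5 rose, Tnc (5.85), Col12a1 (3.40), Postn (3.29), Col6a3 (1.29) and the collagen cross-linker Lox (1.10), and 6 adjusted over the list alone (camera adjusted p = 0.0622). The most abundant members did not pass, with Col1a1 at -0.82, adjusted p = 0.214, Dcn at -0.82, adjusted p = 0.226 and Sparc at -0.75, adjusted p = 0.3. Of 18 glycolysis and hypoxia genes Hk2 (2.02) and the oxygen-regulated factor Hif1a (1.07) rose, and 7 adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.418 with an estimated correlation). Of 16 immediate early genes Ier3 rose by 1.46, adjusted p = 0.0338, also adjusted over the list alone, against a list median of -0.40 and a downward test (camera adjusted p = 0.0622). None of 18 oxidative phosphorylation genes passed (camera adjusted p = 0.14). Markers of other cell types moved as well. Of 7 neutrophil markers 5 rose, S100a9 (9.05), S100a8 (6.99), Hdc (4.55), Mmp9 and Retnlg (ratio 106 (18.8 to 4182)), with 6 rising and Il1r2 falling adjusted over the list alone (camera adjusted p = 2.4e-05, and adjusted p = 0.165 with an estimated correlation). Un-wounded library 1 held no UMI of S100a9 and S100a8, which were at least 91.4 and 67.7-fold higher with un-wounded library 2 left out, against 3 counts in library 1. Of 8 basal keratinocyte markers 3 fell, Col17a1 (-3.12, adjusted p = 0.0411), Trp63 (-1.91, adjusted p = 0.049) and Itga6 (-1.74, adjusted p = 0.0211), and 7 adjusted over the list alone (camera adjusted p = 0.000337, and adjusted p = 0.307 with an estimated correlation). Of 10 macrophage markers Cd68 rose (2.84, adjusted p = 0.0272) and Csf1r fell (-1.14, adjusted p = 0.0105; 0.0957 without un-wounded library 2), with 4 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.0359, and adjusted p = 0.46 with an estimated correlation). None of 4 erythroid markers passed (camera adjusted p = 0.384), with a median log2 change of 3.42 and a pooled CPM ratio of 26.1 (7.098 to 217) for Hbb-bt, from 2 un-wounded UMIs. Without clusters 21 and 22 no proliferation gene of 14 passed, with Birc5 at -0.09 (adjusted p = 0.986) and Stmn1 at -0.31 (0.875), both turned in sign. Ifi27l2a and Ifit1, Postn and Tnc, Cxcl1, Cxcl2, Ccl2 and Ccl8, and S100a8 and S100a9 were then the members that rose. Isg15 (0.188), Bst2 (0.164), Acta2 (0.0829), Timp1 (0.0923), Ccl7 (0.0829) and Csf1r (0.555) had adjusted p above 0.05. Adjusted over the list alone, 11 chemokines, 8 interferon genes, 4 contractile genes, 4 proteases and inhibitors and 4 matrix genes rose without these clusters.

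**Figure D3:**
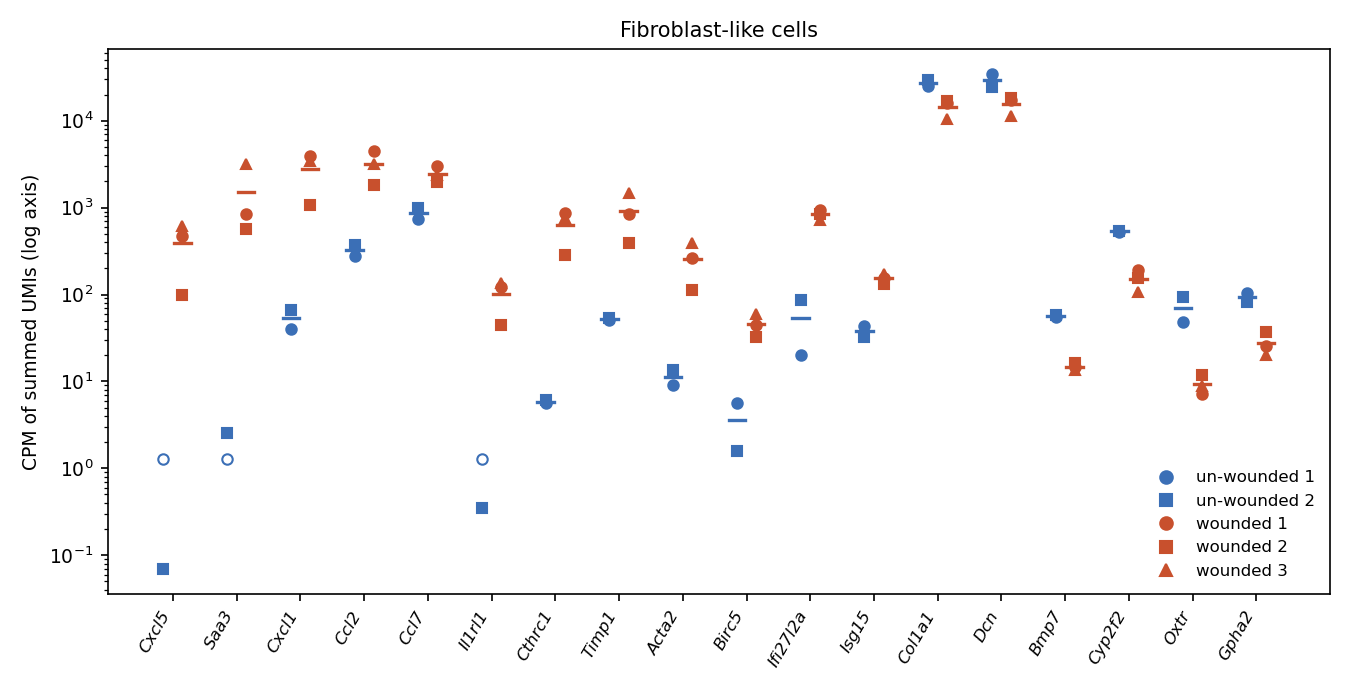
CPM (log axis) of named and listed genes in fibroblast sums, with 1 point per library, un-wounded (n = 2) beside wounded (n = 3), group means as bars, and open symbols at the 3-count floor where a library held no UMI. Groups with an open symbol have no bar. Cxcl5, Saa3 and Cthrc1 lie higher and Oxtr and Bmp7 lower in all 3 wounded libraries, while Col1a1 and Dcn did not pass the test.

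**Figure D4:**
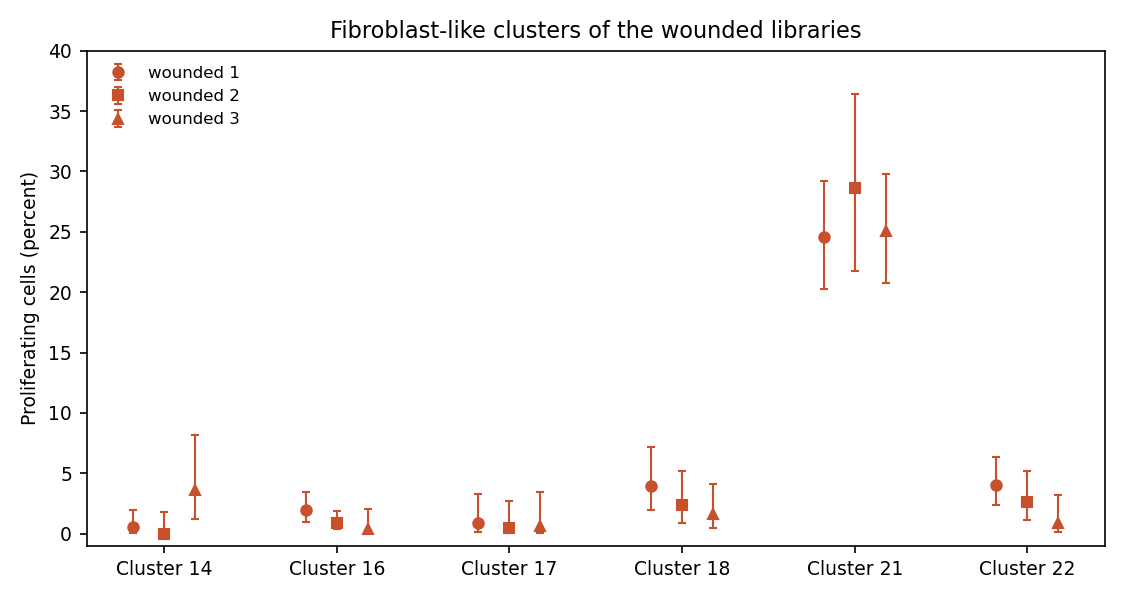
Share of fibroblasts (percent) with UMIs of at least 2 of 18 proliferation genes after thinning to 1500 UMIs, by fibroblast cluster and wounded library, with 95% exact binomial intervals as error bars. Cluster 21 lies at 24.5, 28.7 and 25.1% in wounded libraries 1, 2 and 3, above the other clusters.

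To ask whether wounding acted differently on the 2 tissue layers, the wound effect in fibroblasts was compared with that in basal keratinocytes of the same libraries (n = 2 and 3). H19, an imprinted non-coding RNA (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143), differed by a log2 of 6.58 ± 1.06, adjusted p = 0.000441, with 9.62 in fibroblasts and 3.50 in basal keratinocytes. Rnd1, a regulator of the actin skeleton (ENSMUSG00000054855, chromosome 15, 98663421 to 98677461), differed by 5.62 ± 0.52, adjusted p = 6.33e-07. H19 and Rnd1 were scarce in basal keratinocytes, at 0.332 and 1.90 CPM in un-wounded and 3.41 and 5.26 in wounded skin. Wounded fibroblasts held 183 and 90.5 CPM of them. The cell division genes Cdca3 (ENSMUSG00000023505, chromosome 6, 124829547 to 124833701) and Ccnb2 (ENSMUSG00000032218) differed by 4.20 ± 0.37, adjusted p = 3.32e-07, and 3.78 ± 0.32, adjusted p = 2.98e-07. Cdca3 stood at 1.24 and 32.9 CPM in un-wounded and wounded fibroblasts, and at 56.4 and 87.6 in basal keratinocytes. Ccnb2 stood at 1.90 and 47.0, and at 46.4 and 78.3, so fibroblast levels started low and stayed below the basal ones. Ptgs2, a prostaglandin synthase (ENSMUSG00000032487), and the collagen gene Col8a1 (ENSMUSG00000068196) differed by 3.65 ± 0.36, adjusted p = 1.79e-06, and 3.83 ± 0.92, adjusted p = 0.0167. Col8a1 had 0.332 and 1.03 CPM in un-wounded and wounded basal keratinocytes. On the other side stood the water channel gene Aqp3 (ENSMUSG00000028435, chromosome 4, 41092722 to 41098183), with -4.45 ± 0.61, adjusted p = 6.72e-05, Stfa3, with -4.45 ± 0.81, adjusted p = 0.00158, and Krt17, with -4.09 ± 0.59, adjusted p = 0.00012. Krt5 and Krt14, keratins of basal cells, had -3.76 ± 0.65, adjusted p = 0.000841, and -3.59 ± 0.61, adjusted p = 0.000675, and the chitinase gene Chit1 -3.48 ± 0.59, adjusted p = 0.000675. Krt5 and Krt14 had log2 changes of -2.84 and -2.47 in fibroblast sums, where neither passed, and 0.15 and 0.62 in basal ones, while the basal share of kept cells averaged 31.2% in un-wounded and 8.67% in wounded skin.

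In all, 536 of 13808 genes differed in wound effect, 288 higher and 248 lower in fibroblasts, and 1924 had an unadjusted p under 0.05. Without TMM the split was 292 higher and 136 lower, and the median of all genes was 0.13 instead of 0.03. Of 18 proliferation genes 11 were higher in the fibroblast effect (camera adjusted p = 5.5e-05, and adjusted p = 0.658 with an estimated correlation), and of 12 interferon genes 3 (camera adjusted p = 0.0819). Of 18 glycolysis and hypoxia genes 1 was lower (camera adjusted p = 0.664), with a median of 0.20 and a downward test. No member differed among 16 immediate early genes (camera adjusted p = 0.46), 18 oxidative phosphorylation genes (camera adjusted p = 0.657; median 0.06, downward test) or 7 neutrophil markers (camera adjusted p = 0.574; median -0.19, upward test). None differed among 4 erythroid (camera adjusted p = 0.46) and 11 macrophage markers (camera adjusted p = 0.998). Without fibroblast clusters 21 and 22, 114 genes differed, 25 higher and 89 lower, and H19 (2.00, adjusted p = 0.596), Rnd1 (0.76, 0.726) and Col8a1 (0.35, 0.957) no longer passed. Cdca3 (-0.28, 0.897) and Ccnb2 (-0.18, 0.943) then turned in sign, while Ptgs2, Aqp3, Stfa3, Krt17, Krt5, Krt14 and Chit1 passed. With cluster 12 counted as basal 191 differed, and Aqp3 (0.0759) and Stfa3 (0.111) were lost. Col8a1 was also lost without un-wounded library 1 (adjusted p = 0.192), without wounded library 1 (0.0621), at Leiden resolution 2.0 (0.103) and without the 2 highest cells (0.271), and H19 without the latter (0.0777). Fibroblasts of un-wounded library 1 held no UMI of H19 and Col8a1, so without un-wounded library 2 their difference has no measured size. In fibroblasts they were then at least 146 and 47.3-fold higher in wounded skin, against 3 counts in library 1. Without wounded library 1 Chit1 differed by -5.34. The split turned to 197 higher and 345 lower without un-wounded library 2, and to 286 and 341 without wounded library 1.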

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

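Tests chosen after the result was seen were those of free RNA by fibroblast level, of a few high cells (both), of the lowest other class, of Krt14 and Krt5, of neutrophils by library, of free RNA without the 2 highest cells, and of free RNA by library (S100 genes, and basal sums of wounded libraries 1 and 3). The other tests were set before.

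S100a8 and S100a9 rose in spinous keratinocyte sums of wounded skin. Neutrophils counted among these cells would bring Csf3r, Cxcr2 and Retnlg, but their ratio to both S100 genes was 0.102 of that in neutrophils over the 3 libraries (37 against 6152 UMIs, upper 95% limit 0.14). It was 0.048 in wounded libraries 1 and 2 together (upper limit 0.0791), which argues against neutrophils as the source of the whole sums there. In wounded library 3 it was 0.475 (0.298 to 0.7196), so for that library neutrophils as a source of part of the UMIs stay open. Without the 2 highest cells of each gene, 320 and 56 UMIs of both S100 genes were left in wounded libraries 1 and 2. Csf3r, Cxcr2 and Retnlg had 12 and 3 UMIs in all spinous keratinocytes there. For the remaining cells of these 2 libraries neutrophils thus stay open too. The 2 highest cells held from 59.63 to 97.99% of either gene's UMIs in each wounded library, so a few cells may be the source of most UMIs. They were not the whole source, since without them the log2 fold changes were 8.33 and 8.83 and passed the test. S100a8 plus S100a9 in all spinous keratinocytes stood at 5.301 (5.01 to 5.61), 18.6 (17.5 to 19.8) and 0.985 (0.912 to 1.06) times their CPM in fibroblasts of wounded libraries 1, 2 and 3, by counting limits. This argues against free RNA as the source of the whole sums in wounded libraries 1 and 2. In wounded library 3 free RNA cannot be told apart, since the level allows it while 2 cells held most UMIs. Without the 2 highest cells of each gene the ratio was 0.6404, 0.884 and 0.417 in wounded libraries 1, 2 and 3, so free RNA could be the source of the UMIs in the remaining cells. A response of keratinocytes to wounding stays open, untested.

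Of the genes that rose in basal keratinocyte sums, 134 lay over 10 times higher in another class, by CPM pooled over the libraries of both groups. Free RNA could account for them. Their median share of whole-library CPM was 2.97, 3.51 and 4.42 times that of the 8 fibroblast markers in wounded libraries 1, 2 and 3, above the bound of 2 set before for its exclusion. The 95% bootstrap limits over genes, a spread chosen after, were 2.13 to 4.51, 1.996 to 7.502 and 2.84 to 8.84. That bound was wrong for 2 reasons. The 134 genes were chosen for their rise in basal sums, which favours a high basal share, and the markers were not. The level of the genes in other classes does not bear it out either, since by counting limits 42, 18 and 48 of the 134 lay above the lowest of 6 other classes, and 92, 116 and 86 were not shown to. The median gene stood in basal cells at 0.504, 0.323 and 0.388 times its CPM in fibroblasts. Free RNA and expression therefore cannot be told apart for these genes as a set in any wounded library, since most were not shown to lie above the level in cells of other classes. A response of basal cells to wounding stays open, untested.

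Proliferation genes rose in fibroblast sums of wounded skin. Free RNA from cycling keratinocytes would bring Krt14 and Krt5, which had log2 fold changes of -2.47 (SE 0.998) and -2.84 instead, and this argues against it. Clusters 21 and 22, found mainly in wounded libraries, had proliferating shares of 13.7, 11.6 and 16.03% in wounded libraries 1, 2 and 3, against 1.77, 0.972 and 1.35% in the other fibroblast clusters, a gap of at least 10.6 points. Cluster 21 alone reached 24.5, 28.7 and 25.1% and cluster 22 4.01, 2.66 and 0.893%, consistent with cycling cells in cluster 21. Whether cluster 21 arises from fibroblasts of un-wounded skin was not tested, and a response to wounding stays open.

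The wound effect differed between fibroblasts and basal keratinocytes in 536 genes by the interaction test. Of the genes that met the rule for naming, those with the largest differences above 0, fibroblast minus basal on the log2 scale, were H19 (6.58), Rnd1 (5.62), Cdca3 (4.20), Col8a1 (3.83), Ccnb2 (3.78) and Ptgs2 (3.65). Below 0 they were Aqp3 (-4.45), Stfa3 (-4.45), Krt17 (-4.09), Krt5 (-3.76), Krt14 (-3.59) and Chit1 (-3.48). In fibroblast sums Aqp3, Krt17 and Chit1 had log2 changes of -1.60, -2.37 and -3.65. The values of Krt14 and Krt5 do not by themselves show a response of fibroblasts, since pooled CPM was also lower in wounded than un-wounded cells of some other classes, untested. Krt14 had 297 and 113 in fibroblasts, 336 and 69.9 in dendritic cells, 361 and 102 in macrophages and 315 and 90.6 in the class named NK cells, but 943 and 914 in that named T cells and 494 and 473 in vascular endothelial cells. Krt5 had 177 and 42.3, 192 and 25.04, 290.0 and 34.7, 286 and 28.01, 429 and 452, and 380.1 and 134 in the same order. Among barcodes with under 200 genes, which entered no comparison, 59 in wounded library 2 and 5 in wounded library 3 had medians of 97.5 and 97.6% globin UMIs, and un-wounded libraries had none. The unnamed cluster 28, led by the osteoclast genes Acp5, Mmp9, Atp6v0d2 and Nfatc1, made up 0.538, 1.502 and 1.304% of kept cells in wounded libraries 1, 2 and 3, and 1 cell in each un-wounded library. The unnamed cluster 30, led by the muscle progenitor genes Myog, Myf5 and Myod1, made up 0.751, 0.592 and 2.81%, with 0 and 1 cells in un-wounded libraries.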

How the results depend on the processing

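Naming without a score margin, sums without the 2 highest cells, and fibroblasts without clusters 21 and 22 were chosen after seeing the data; the other alternatives were planned. Among named genes, direction and side of the threshold held in 720 of the basal, 699 spinous, 823 fibroblast, 518 whole-library and 132 interaction results over all alternatives. Calls were lost in 44, 25, 23, 53 and 10 and gained in 32, 31, 34, 33 and 0. The log2 fold change turned in sign, without a call in either fit, in 40, 42, 20, 33 and 0. Changed genes were, with DESeq2, 2657 in whole libraries and 122 in basal keratinocytes; with no filter on low counts, 700 in whole libraries, 367 in basal and 451 in spinous keratinocytes and 1894 in fibroblasts; and without TMM 129 in basal keratinocytes. Without genes over 10 times higher in another class 75 basal and 103 spinous genes changed, fewer genes being tested. Without a score margin 59 basal genes changed and 191 differed in wound effect. Without clusters 21 and 22 the counts were 42 in fibroblasts and 114 for the wound effect, and Stmn1 (-0.31), Birc5 (-0.085), Cdca3 (-0.28) and Ccnb2 (-0.18) turned in sign, as cells highest in these genes were removed. Sums without the 2 highest cells gave 244 basal, 196 spinous and 934 fibroblast genes. With an estimated correlation 0 lists passed in each of whole libraries, basal, spinous and fibroblast tests, against 12, 8, 8 and 9 at the preset one. In basal sums Hba-a2 (13.77) and Hba-a1 (12.54) turned with doublets kept, on UMIs of wounded library 2 alone, and by the same values with Scrublet's threshold. At Leiden resolution 2.0 the T cell difference was 0.891 and the unnamed one -2.41 points, and the unnamed one 0.282 without a score margin. Where no reason is given, the cause was not tested.

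Leaving out 1 library at a time gave 0 to 2141 changed genes in whole libraries, 131 to 284 in basal keratinocytes, 41 to 301 in spinous keratinocytes, 367 to 1313 in fibroblasts and 432 to 651 for the wound effect; a lone un-wounded library is then assumed to vary like the others. Differences in class shares ranged, in percentage points, over -35.4 to -9.63 (basal), -14.8 to -8.35 (spinous), -3.54 to 27.1 (fibroblast), 6.302 to 16.1 (macrophage), 5.83 to 14.4 (dendritic), 1.49 to 6.56 (NK), -1.64 to -0.372 (T), 0.761 to 1.92 (neutrophil), 0.376 to 0.817 (mast), 0.609 to 4.51 (pericyte), 0.587 to 1.41 (endothelial), 1.08 to 1.39 (muscle), -5.55 to -1.03 (root sheath), -0.826 to 0.303 (sebocyte), -0.6796 to 0.6502 (Langerhans) and -8.74 to -5.03 (unnamed). The proliferating share ranged over 1.903 to 3.43 and sub-clusters 0 to 4 over 3.36 to 10.6, -24.5 to 7.09, -46.4 to 17.6, -26.7 to 6.88 and 21.1 to 31.5.

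With the replicate number as a replicate block, edgeR called 0 genes in whole libraries (4154 at an unadjusted p under 0.05, and 2657 by DESeq2 without a block), 525 basal, 391 spinous and 1614 fibroblast genes, and Krtdap turned in basal sums (-1.07). Only 2 numbers occur in both groups, so the block rests on 2 pairs that the labels do not describe as paired. Deviations of same-numbered libraries from their group means correlated over genes at 0.465 and 0.425 in whole libraries. The values were 0.344 and 0.233 in fibroblasts, 0.289 and 0.223 in spinous and 0.2 and 0.13 in basal keratinocytes. Deviations of the 2 un-wounded libraries mirror each other, so these pairs are not separate evidence. A link between same-numbered libraries stays open, and the main tests leave it out. Depth limits wounded library 2, whose basal sum holds 30 cells and 223565 UMIs. Macrophage, vascular endothelial and T cell comparisons and their alternatives were not run, since some library held under 30 cells.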

Other observations

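The values below were chosen after the data were seen and were not tested between groups; intervals are 95% counting limits of pooled cells. The 43 macrophages or monocytes of un-wounded skin and the 1636 of wounded skin had different pooled values in genes of both activation lists, but 39 of the 43 came from un-wounded library 2 and 938 of the 1636 from wounded library 3. At Leiden resolution 2.0 a macrophage cluster led by C1qa held 3 and 25 un-wounded and 83, 43 and 216 wounded cells. One led by Arg1 held 1 and 3 against 98, 253 and 414, and one led by Lyz2 0 and 11 against 108, 121 and 309. The pooled values thus compare different mixes of clusters. Arg1, an arginase of tissue repair, had 0 UMIs un-wounded (up to 18.8 CPM) and 323 CPM (311 to 334) wounded, and the anti-inflammatory cytokine Il10 0 and 213 CPM (204 to 222). Other genes of the alternative list lay the other way, with Mrc1, the mannose receptor, at 859.9 and 151 CPM in un-wounded and wounded cells, the folate receptor Folr2 at 427 and 87.7 and the scavenger receptor Cd163 at 173 and 7.704. In the classical list the interleukin Il1b had 2244 and 6035 CPM, the prostaglandin synthase Ptgs2 96.7 and 1108 and the neutrophil attractant Cxcl2 5256 and 17747. The chemokine Ccl8 had 12512 and 1019, and the MHC class II gene H2-Aa 8604 and 6019.

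In 39 un-wounded and 211 wounded vascular endothelial cells, the leukocyte adhesion molecule Vcam1 had 21.7 CPM (5.92 to 55.6) and 224 CPM (204 to 246), and the tip cell gene Esm1 5.43 CPM (0.137 to 30.3) and 85.8 CPM (73.4 to 99.8). E-selectin (Sele) had 380.1 CPM (296 to 480.3) and 89.4 CPM (76.7 to 104). In 135 un-wounded and 51 wounded cells of the class named T cells, 99 of the 135 from un-wounded library 1, the granzyme Gzmb had 12.3 CPM (3.36 to 31.6) and 215 CPM (158 to 286), and Tnf 148 CPM (109 to 196) and 63.98 CPM (34.98 to 107). Gpha2, which fell in whole libraries, basal keratinocytes and fibroblasts, had pooled values of 35.1 and 9.804 CPM in un-wounded and wounded spinous keratinocytes, 12.5 and 1.61 in dendritic cells, and 138 and 123 in outer root sheath or bulge keratinocytes.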
